A study of Homo sapiens with 9 samples.

How the data were processed

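The data are gene expression microarrays of WM266-4 cells, an established human melanoma line from a metastasis, here carrying GFP. Per the labels, cells were transfected by lipofection with a mimic of the microRNA miR-199a-3p at 0.5 nM or 0.25 nM, or with a control microRNA at 0.5 nM, as biological triplicates, and total RNA was taken 48 h later. The 9 arrays fall into 3 groups of 3. The control was given at 0.5 nM, so the 0.25 nM group has no control of its own dose.

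RNA was labelled with a whole-transcript biotin kit, per the labels' protocols. The submitters' processing notes name oligo, affy and RMA (background correction, quantile normalization and median polish); versions, order of steps and genome build are not given in the sources used here, so no coordinates are printed. The deposited values are log2 intensities in 1 table of 44629 rows and 9 columns, with array medians from 4.94 to 5.21 over all rows. Gene values were not centred. Precision rests on 3 arrays per group and on the noise between groups, not on read depth.

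The annotation table of the platform gives exactly 1 gene symbol to 15835 rows and several to 0; the remaining 28794 rows are unnamed here. All 15835 gene IDs matched the current reference gene table. Where a gene had several rows (651 genes) the brightest over all arrays was kept, which left 14812 genes.

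The values themselves bear on every test. Exactly equal values were found on all 3 arrays in 47.8% of rows of the control group, 48.6% of the 0.5 nM group and 42.0% of the 0.25 nM group, while no pair of arrays from different groups shared an equal value in any row. In a simulated median polish of 20 probes per row, 55.9% of rows tied on all 3 arrays when groups were summarised apart and 0.50% when 9 arrays were summarised together; with groups apart the simulated noise between groups was 3.11 times larger, and that within groups smaller. The deposited values thus have the form of groups normalized and summarised apart, a step no label records. Also, in replicate 3 of the 0.25 nM group no value has 0 as its first decimal, against 4178 to 4774 values in the other columns. Of 2695 rows in which replicates 1 and 2 of that group are equal with 0 as first decimal, 2351 (87.2%) equal replicate 3 once zeros after the point are dropped. Values of fewer than 10 digits in that column were therefore left out (19.1% of genes there). The design fixed before the data were examined used the values as deposited. That fit is kept as an alternative, and the model called planned below is that design with these values left out.

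Each comparison was tested with limma 3.58.1 in R 4.3.3, in 1 model with a mean per group over 9 arrays, two-sided, with Benjamini-Hochberg adjustment over 14812 genes and a threshold of 0.05. Because that model takes its error from the spread within groups, a further test was added after the data were seen. It treats each group as 1 unit: limma with an intensity trend was fitted to the 3 group means, control against both doses. A gene's own error comes from its difference between the doses. In limma it is then moderated toward the error of genes of similar level (35.9 prior degrees of freedom). Most of the error is thus borrowed from other genes. Arrays were first shifted to the same median, the shift already planned as an alternative. The group-level test was run in 30 other settings on genes and once on all rows, many of them tried before this one was chosen. Their counts are given with the sensitivity results. This setting was kept for its planned shift and not for its count. Its intensity trend had been planned only as an alternative of the limma model, and without the trend the group-level test called 0 genes. Fold changes are given with arrays shifted to the same median, since the median change over all genes was 0.10 (0.5 nM) and 0.14 (0.25 nM) log2 units. The shift took 0.09 and 0.16 from the change of genes with no missing value.

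On simulated data for both doses against control (14812 genes, 5 runs, 100 genes changed 1.5-fold and 100 changed 2-fold), with no noise between groups, the planned limma test found all 100 of each size on average. With noise between groups as measured between the doses it found 98.6 and 100 but also called 63.8% of unchanged genes. The group-level test then found 21.6 of the 1.5-fold and 65.2 of the 2-fold genes, with 6.0 false calls per run. The simulated noise was normal, equal in all groups and set by level, as that test assumes, with no offset between arrays. Its false calls may therefore be too few for the real data.

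Gene lists (27, fixed before the data were examined) were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it; fry ran with missing values set to the group mean, which narrows the spread slightly. Genes named for the planned tests are the 12 with the largest rise and the 12 with the largest fall per dose (5 and 5 between doses) among those past the threshold whose arrays do not overlap between groups, leaving out unnamed loci, small RNAs, symbols that end as those of pseudogenes do and similar symbols; members of the list of reported targets may also be named. All genes past the group-level test are named, as are replicate 1 genes by size, both chosen after their values were seen.

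Replicate numbers are shared by the groups in the labels. Deviations from group means correlated at 0.14 to 0.59 in same-numbered arrays of different groups, every pair above 0.1, and at -0.48 to 0.36 in differently numbered arrays, so the numbers were taken to pair the arrays. Only 5 of 9 arrays correlated best with their own number in both other groups, so replicates 2 and 3 are hardly told apart and the pairing rests mostly on replicate 1; the pairing comes from the values, since the labels name no shared day or batch. A planned analysis of seed matches in 3-prime UTRs needs transcript sequences and was not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.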

Results

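Whole-transcript arrays were collected from WM266-4 melanoma cells 48 h after transfection with a miR-199a-3p mimic at 0.5 nM (n = 3) or 0.25 nM (n = 3), or with a control microRNA at 0.5 nM (n = 3). Values are log2 RMA intensities, and 14812 genes were tested. The comparisons ask which transcripts differ from the control microRNA at each dose, whether the doses share their changes, and whether they differ from each other. The microRNA's own genes do not check the transfection, since a mimic need not be labelled by this assay: MIR199A1 lay 0.33 above control at 0.5 nM and -0.42 from it at 0.25 nM, and MIR199B at -0.52 and -0.14, both near mean levels of 3.13 and 2.69.

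**Figure D1:**
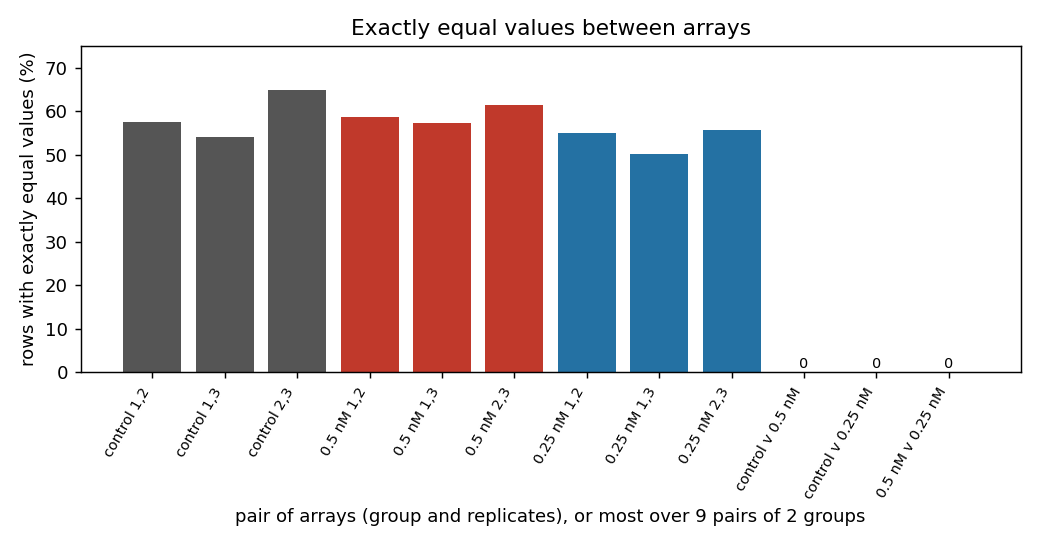
Percent of the 44629 rows with exactly equal values, for each pair of arrays within a group (coloured bars, replicate numbers below) and, for each pair of groups, the most over 9 pairs of arrays (right). Pairs within a group share 50.1% to 64.9% of rows and pairs between groups share 0.

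Taking both doses against control, 19 genes passed the group-level test, which was added after the data were seen and counts each group as 1 unit: 15 fell and 4 rose. VAMP3, a vesicle SNARE of recycling endosomes, fell from 10.27 ± 0.011 in control (SD, n = 3) to 9.55 ± 0.21 at 0.5 nM (n = 3) and 9.13 ± 0.073 at 0.25 nM (n = 2). With arrays shifted to the same median these are changes of -0.81 and -1.30 (limma adjusted p = 9.22e-05). RNF14, a RING-type ubiquitin ligase, changed by -0.88 and -1.27 (limma adjusted p = 9.22e-05), and SGPL1, the lyase that degrades sphingosine phosphate, by -1.08 and -1.04 (limma adjusted p = 0.00341). ITPK1, an inositol phosphate kinase, changed by -0.67 and -1.10, and L1CAM, a cell adhesion molecule, by -0.64 and -0.97. Most of these genes were well expressed: 17 of the 19 lay above the median level of all genes, all but FAM30A and TXNDC9. The intensity trend gives bright genes a smaller error (SE 0.14 for VAMP3 against 0.30 for FAM30A), so the test favours them.

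The other genes that fell were SLC49A4, PON2, a paraoxonase, CD2AP, an adaptor at sites of membrane and actin remodelling, C6orf62, POLR3G, a subunit of RNA polymerase III, AMZ2, CISD2, TMEM245, HSDL1 and FOS, a component of the AP-1 transcription factor whose control arrays spread by an SD of 0.38. Those that rose were FAM30A (1.68 at 0.5 nM and 1.37 at 0.25 nM), ZNF287 (0.97 and 0.84), AK5, an adenylate kinase (0.80 and 1.01), and TXNDC9 (1.41 and 0.87). Of the 15 that fell, 13 lay further from control at 0.25 nM than at 0.5 nM, with medians of -0.64 and -0.94 for 0.5 nM and 0.25 nM. The number depended on the setting: over 30 others run on genes the test called 0 to 47, and on all rows of the table it called 83 rows. It called 0 when 0.25 nM replicate 1 was left out, 2 when replicate 1 was left out of every group and 12 when 0.25 nM replicate 3 was left out. Setting 0.25 nM apart in place of control called 13 genes, and setting 0.5 nM apart called 3.

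**Figure D2:**
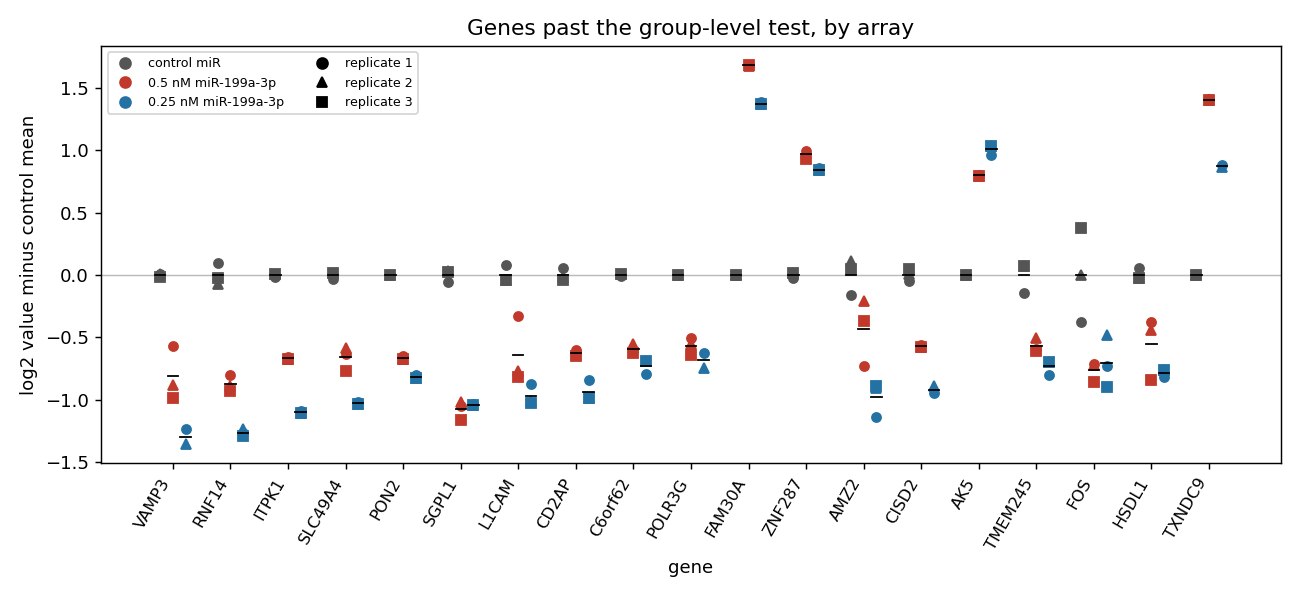
Log2 value of each array minus the mean of the control arrays, after arrays were shifted to the same median, for the 19 genes past the group-level test. Colours are groups, symbols are replicate numbers and black bars are group means; in VAMP3 the means lie at -0.81 (0.5 nM) and -1.30 (0.25 nM), and for FAM30A at 1.68 and 1.37.

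In the planned limma model, 9984 genes passed for both doses against control, 7458 higher and 2526 lower. After arrays were shifted to the same median 4713 were higher and 4795 lower. This model takes its error from arrays that tie exactly within groups, so its p-values are too small as a measure of the difference between treatments. In simulated data with the noise seen between doses it called 63.8% of unchanged genes.

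At 0.5 nM, the genes that rose most in the planned model were FAM30A (1.68), FANK1 (1.55), TXNDC9 (1.41), ZNF471, LARRPM, MED27, a Mediator subunit, SIRPG, CLDN16, a claudin of tight junctions, TMCO2, ARHGAP15, CCNYL4, annotated as a transcribed pseudogene, and USP44, down to 1.20. Those that fell most were TRIM64 (-1.99), CCL11, the chemokine eotaxin (-1.79), PRAMEF2, CFHR4, SLFN14, DUXA, SH2D1A, USP17L15, GCSIR, ZNF347, RAET1L and CTAG2, a cancer-testis antigen (-1.15). Of these 24 genes, 23 lay below the median level of all genes, 6.24, and FAM30A and TXNDC9 also passed the group-level test. Among reported targets of miR-199a-3p, with p-values here from the fit with arrays shifted to the same median, MAP3K11, a kinase upstream of JNK, fell by 0.44 (limma adjusted p = 8.23e-09), HOMER1 by 0.25, CD44 by 0.19, TAOK1 by 0.17 and YAP1 by 0.07. YAP1 lost its call with the replicate number as a block (limma adjusted p = 0.0404 without and 0.0545 with it). Without the shift HOMER1, CD44, TAOK1 and YAP1 did not pass (limma adjusted p = 0.0701, 0.190, 0.0517 and 0.473). YAP1 then lay at 0.02. CLIC5 rose by 0.48 (limma adjusted p = 5.80e-09), PTGS2 by 0.16 (limma adjusted p = 6.93e-05) and LIN28B by 0.05. CLIC5 and LIN28B had low signal, at mean levels of 3.36 and 3.49, and CLIC5 tied exactly within every group. The receptor tyrosine kinase MET, at -0.33 ± 0.31 (SE), did not pass (limma adjusted p = 0.390) but did with the replicate number as a block, at an SE of 0.079 (limma adjusted p = 0.0157). PAK4 at -0.21 likewise passed only with the block (limma adjusted p = 0.0862 without and 0.0240 with it). The receptor tyrosine kinase AXL at -0.30 (limma adjusted p = 0.110) did not pass, nor did MTOR at 0.01 (limma adjusted p = 0.696). MTOR, APOE, ZEB1 and KDM6A passed as higher only without the shift, MTOR at 0.10 (limma adjusted p = 0.00297). In the group-level test of both doses no reported target passed, MAP3K11, CLIC5, PTGS2 and PAK4 included (limma adjusted p = 0.341, 0.964, 0.978 and 0.890).

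For 0.5 nM against control 9638 of 14812 genes (65.1%) passed, 6665 higher and 2973 lower, or 4917 and 4455 with arrays shifted to the same median. Of 16 measured reported targets, 7 were higher, 1 lower and 8 did not pass, a split that turned to 3 higher and 5 lower with arrays shifted (7 and 3, or 3 and 6 shifted, with the replicate number as a block); 7 passed when adjusted over the list alone. Of 10 epithelial and keratinocyte markers, 2 were higher and 7 lower, including KRT1 at -0.69 and DSG3 at -0.50, which lay higher at 0.25 nM, by 0.38 and 0.22. The SE of DSG3 without the shift, 0.00085, was that of TXNDC9, whose arrays tied exactly within every group. Of 6 fibroblast markers 4 were higher and 0 lower, also with arrays shifted. Of 12 genes of cholesterol synthesis and uptake 7 were higher and 0 lower (5 and 1 with arrays shifted), including INSIG1 at 0.19 and SQLE, squalene epoxidase, at 0.15. None of the 27 lists stood apart from other genes by camera (0 adjusted and 1 at an unadjusted p under 0.05, smallest adjusted p = 0.301; 0 with an estimated correlation), while fry, which does not compare a list with other genes, called 25. The counts and the ranks used by camera rest on the spread within groups alone, as for both doses together. The 0 lists therefore do not show that no list changed. By median change against 10000 random lists of similar level, cholesterol synthesis, YAP and TAZ targets and MAPK pathway output stood at percentiles 99.4, 99.3 and 99.6. Epithelial and keratinocyte markers stood at 0.32. The other lists stood between 4.09 and 97.0, all not adjusted for the 27 lists.

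At 0.25 nM, the genes that rose most in the planned model were FBXW10 (2.02), ARL14EPL (1.66), PSG5, a pregnancy-specific glycoprotein (1.64), LRRC17, LCE3E, ARGFX, FAM30A, PSG4, RDUR, ZNF679, CHST2, a sulfotransferase, and CD38, an ectoenzyme that consumes NAD (1.25). Those that fell most were HNRNPCL1 (-1.72), TAT, tyrosine aminotransferase (-1.65), SH2D1A, CDA, cytidine deaminase, FAM245A, MBOAT4, VAMP3, ENPP4, FLG2, DOK6, RNF14 and ELSPBP1 (-1.26). VAMP3 and RNF14, at mean levels of 9.71 and 8.93, were the only 2 of these 24 above the median level. Among reported targets, again with arrays shifted, MAP3K11 fell by 0.66 (limma adjusted p = 1.57e-09), MTOR, the growth-signalling kinase, by 0.40 (limma adjusted p = 2.53e-06) and TAOK1 by 0.33 (limma adjusted p = 2.21e-05), as did HOMER1 by 0.35, APOE by 0.21 and YAP1 by 0.10. The 4 that rose were LIN28B by 0.32 (limma adjusted p = 2.12e-06), CLIC5 by 0.18, ZEB1 by 0.12 and PTGS2 by 0.10. Of these, LIN28B and CLIC5 had low signal, at mean levels of 3.49 and 3.36. Without the shift HOMER1, APOE and YAP1 did not pass (limma adjusted p = 0.0545, 0.372 and 0.0735), with YAP1 at 0.06. CD44, at 0.04 with the shift, passed as higher without it, at 0.20 (limma adjusted p = 0.0209). PAK4 at -0.39 passed with arrays shifted (limma adjusted p = 0.0139) and not without (limma adjusted p = 0.0870), and with the block it passed in both (limma adjusted p = 0.00284 and 0.0239). MET at -0.65 ± 0.31 (SE; limma adjusted p = 0.104) and AXL at -0.38 (limma adjusted p = 0.0548) did not pass, but with the replicate number as a block both did, MET with an SE of 0.079 (limma adjusted p = 0.00118) and AXL (limma adjusted p = 0.0294). The block leaves the error within groups that tie exactly, and in the group-level test neither passed (limma adjusted p = 0.304 and 0.622). Nor did MAP3K11, MTOR, TAOK1 and LIN28B pass it (limma adjusted p = 0.341, 0.920, 0.799 and 0.980), and 0 of the 16 reported targets did.

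For 0.25 nM against control 10046 genes passed, 7517 higher and 2529 lower, or 4486 and 5025 with arrays shifted to the same median. Of 16 reported targets 5 were higher and 3 lower, or 4 and 7 with arrays shifted (6 and 6, or 4 and 9 shifted, with the replicate number as a block), and 8 passed when adjusted over the list alone. Of 10 epithelial and keratinocyte markers 6 were higher and 4 lower, or 3 and 5 with arrays shifted. Of 6 fibroblast markers 5 were higher and 0 lower, or 4 and 0 with arrays shifted. Of 12 genes of cholesterol synthesis and uptake 9 were higher and 0 lower (6 and 0 with arrays shifted), including MSMO1 and INSIG1, both at 0.35. Of 12 YAP and TAZ targets 7 were higher and 0 lower (6 and 0 with arrays shifted), including AJUBA at 0.48 and CCDC80 at 0.82. None of the 27 lists passed camera (0 at an unadjusted p under 0.05, smallest adjusted p = 0.888, 0 with an estimated correlation), while fry called 25. Camera again ranked genes by the error within groups. By median change against random lists, cholesterol synthesis, apoptosis regulators, mitosis and YAP and TAZ targets stood at percentiles 99.9, 98.6, 98.4 and 98.2. Lysosome and autophagy stood at 2.38 and the reported targets at 2.60. The other lists stood between 3.08 and 94.7, all not adjusted for the 27 lists. The control of this comparison held 0.5 nM of small RNA against 0.25 nM in the treated cells, so dose of small RNA and mimic changed together.

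The reported targets were also set against all other genes in the group-level test. On the mean of the doses 11 of 16 were lower, and 8 were lower at both. By limma camera the list did not pass (adjusted p = 0.0661). Cholesterol synthesis and YAP and TAZ targets lay higher and oxidative phosphorylation lower (camera adjusted p = 0.0755 for each), and none passed. By median change against random lists of similar level, these lists stood at percentiles 99.9, 98.9 and 2.34. Mitosis, apoptosis regulators and DNA replication stood similarly high, at 98.85, 98.82 and 97.2, and epithelial and keratinocyte markers low, at 2.06. The other lists, the reported targets included, stood between 4.81 and 93.3, all not adjusted for the 27 lists. The median of the reported targets, -0.0791, lay inside the interval of random lists, -0.126 to 0.0891.

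The changes of the doses against their shared control correlated across genes at r = 0.52, with 67.8% of genes of the same sign; simulated unchanged groups against the same controls gave r = 0.50 and 66.7%. Across 7406 genes above the median level, r was 0.55 against 0.50 simulated, and the covariance 0.0257 against 0.0212. Over all genes the covariance was 0.0499 against 0.0462 (SD of the simulation 0.00117). In the planned model 4979 genes were higher and 1294 lower at both doses, where independent lists of these sizes would share 3382 and 508. With arrays shifted to the same median these counts were 2806 and 2793, 5599 in all. In 20 simulations of unchanged groups against shared controls, added after the data were seen, they were 2597 (SD 127) and 2558 (SD 125) on average. The simulated total was 5155 (SD 55.9). An overlap of most of this size can thus arise with no effect of the mimic, where the noise is as large as the difference between the doses, which may itself hold a response that differs by dose. The remainder of the total exceeds the spread of the simulation, less clearly so in each direction alone. It depends on the same assumption, and genes are not independent replicates.

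Between the doses, ENPP4 (-1.28 at 0.25 nM and 0.10 at 0.5 nM against control), FAM245A, DOK6, an adaptor of receptor tyrosine kinases, TAAR6 and C1QTNF7 were furthest above at 0.5 nM. FBXW10, LCE3E, a cornified envelope protein, USP17L15, ORM2, an acute-phase plasma protein, and CHST9 were furthest below. All 10 lay below the median level. In the planned model 9281 genes passed, 3961 higher and 5320 lower at 0.5 nM, or 5182 and 4028 with arrays shifted to the same median. No list passed camera, again with the error within groups (0 at an unadjusted p under 0.05, 0 with an estimated correlation, 25 by fry). The spread over genes between the doses (SD 0.31 log2 units) was close to that of either dose against control (0.31 for each): the variance between the doses was 0.965 of that of a dose against control (95% interval 0.937 to 0.995 over resampled genes).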

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

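Except for the splits of the arrays, the tests in this part were chosen after the results were seen; how far the 84 splits can be compared was also judged after their counts were seen. For 0.5 nM against 0.25 nM, 9281 genes passed the planned limma test, a difference between groups that were given the same mimic. Among rows of the array without a gene name here, which were not among the genes of the main comparisons, 39 passed the group-level test of both doses against control.

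The first pattern is that most genes passed the planned test in every comparison. A broad response shared by the doses needs the doses to resemble each other, but the variance over genes between doses was 0.965 of that between a dose and control (95% interval 0.937 to 0.995 over resampled genes), which argues against it as the whole cause. Groups normalized and summarised apart are consistent with the exact ties, at least 22346 rows in each pair of arrays of 1 group and 0 between groups. A response that differs by dose stays open beneath that noise. Of the 84 splits of 9 arrays into 3 and 6, 1 gave as many genes as the real one (5739 genes, highest other 4703). That highest other set the 0.25 nM group apart and setting 0.5 nM apart gave 3803, while splits that mixed groups gave at most 127, the split by replicate 1. The calls follow the groups whichever is set apart, so only the 3 splits that keep groups whole compare with the real one, too few for a share under 0.05.

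For each comparison of 3 against 3 the 10 splits are too few for a share under 0.05: 1 of 10 gave as many genes, with 9935 for 0.5 nM against control, 10000 for 0.25 nM against control and 9258 between doses, and a highest other of 0 each.

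The second pattern is that more genes fell than rose in the group-level test, VAMP3, RNF14 and SGPL1 among them. Lost zeros in 1 column cannot be told apart as a contributor: without that array 10 of 12 genes fell, but the count was below 19 by more than 1.5 times. Of the 3 ways to set 1 group apart, 1 gave as many genes (19, highest other 13), and 3 ways are too few for a share under 0.05. A response to the mimic is consistent with the unnamed rows, of which 82.1% fell (32 of 39, exact binomial 95% interval 66.5% to 92.5%, rows taken as independent), although they share the control arrays with the pattern. Of all 972 genes at an unadjusted p under 0.05 in that test 488 (50.2%) fell, no excess of falls, and of the 555 of these above the median level 339 (61.1%) fell. As a hypothesis, these genes may include transcripts lowered by the mimic; matches to its seed were not tested.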

How the results depend on the processing

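The group-level test and all its settings were chosen after the data were seen. So was the rule that left out values of fewer than 10 digits in 0.25 nM replicate 3, which the model called planned here uses. The fit fixed beforehand used the values as deposited. It called 8979 genes for 0.5 nM against control, 9672 for 0.25 nM, 9430 for both doses and 8796 between doses. Counts of the planned limma test stayed within 1.5 times of their main value under an intensity trend, the mean of rows, quantile normalization again, arrays shifted to the same median, the groups compared alone, array weights and values as deposited. With genes above the median level alone they were 3937 (0.5 nM against control), 4309 (0.25 nM), 4203 (both doses) and 3765 (between doses), and with all rows 29486, 30293, 30272 and 28915, as fewer or more rows were tested; with a change of at least 1.5-fold they were 1122, 1277, 838 and 925. Leaving out each array gave 8977 to 9470, 9440 to 10135, 9219 to 10285 and 8726 to 9350. With the replicate number as a block the counts were 9894, 10419, 10291 and 9563, with 284, 219, 247 and 274 calls lost and 540, 592, 554 and 556 gained. The block changed no call of a list or of a gene named by the planned rule. Of the 16 reported targets, tested with the block after the data were seen, it added 2 at 0.5 nM and 4 at 0.25 nM; with arrays shifted it added 2 and 2 and ended 1 at 0.5 nM, YAP1 (limma adjusted p = 0.0404 without and 0.0545 with it). The list counts were 0 in every planned setting, and 0 to 0 with each array left out. All of these settings took the error within groups, so the zeros do not show that no list changed. The agreement of the doses was r = 0.55 above the median level and 0.51 to 0.54 with each array left out.

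The group-level count of 19 was far less stable. It was 0 with no intensity trend (866 genes at an unadjusted p under 0.05) and 0 with no shift to the same median, with or without a robust spread or genes above the median level alone. It was 41 with group means shifted to the same median (33 with a robust spread), 35 with values as deposited, 39 with the mean of rows, 83 with all rows, and 38 with quantile normalization again above the median level (44 with a robust spread). A first, mistaken rule that left out values of under 9 decimals gave 2, or 41 with group means shifted. Without replicate 1 in every group it was 2, and leaving out each array gave 0 (0.25 nM replicate 1) to 47 (0.5 nM replicate 3). The cause was not tested. More genes fell than rose in all 24 settings on genes that called any, and the 19 genes kept their direction in every one in which they were tested. All settings reuse the same arrays, and genes selected for large changes could hardly reverse, so neither count is separate support. Every one of the 19 lost its call in at least 6 settings: VAMP3 and RNF14 passed in 24 of 30, AMZ2 in 11 and TMEM245 in 10. With 1 array left out, VAMP3 passed in 8 of 9 fits, with adjusted p up to 0.330, AMZ2 in 4 and TMEM245 in 3. Genes named by the planned rule changed neither direction nor call. They were chosen for large changes and every setting kept the error within groups, so this is not separate support. Few of them passed the group-level test: 2 that rose and 0 that fell at 0.5 nM, 1 and 2 at 0.25 nM, and 0 between doses. Planned tests of seed matches were not run, for want of transcripts. Low signal limits the genes named at each dose, nearly all below the median level.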

Other observations

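The tests in this part were chosen after the results were seen. Replicate 1 differed from replicates 2 and 3 in a similar way in every group, whatever was transfected: over all genes the difference correlated between groups at 0.50 to 0.59. With group as a term in limma, 804 genes differed at an adjusted p under 0.05, 215 higher and 589 lower in replicate 1. Replicates 2 and 3 set apart gave 0 each (166 and 146 at an unadjusted p under 0.05). With replicate 1 in the comparison its difference enters the error, so these counts do not show replicates 2 and 3 to be alike. STC1, a secreted glycoprotein, was higher by 1.51 ± 0.092 (SE), RAMP2, a receptor activity-modifying protein, by 1.13 ± 0.053, and the angiogenic factor VEGFA by 0.89 ± 0.072. FGL2 was lower at -2.26 ± 0.20, the transcription factor EBF3 at -1.63 ± 0.077, the matrix proteoglycans FMOD and LUM at -1.58 and -1.55, and the collagenase MMP1 at -1.33. MET, a reported target of the mimic, was higher in replicate 1 by 0.67, which widens its spread within groups.

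Among the fixed lists, DNA replication genes were lower in replicate 1: 10 of 20 fell and 0 rose, including MCM7 at -0.55 and UHRF1 at -0.47 (camera adjusted p = 1.10e-12, and adjusted p = 5.25e-09 with an estimated correlation). MYC and ribosome biogenesis genes fell in 7 of 12, including NOLC1 at -0.33 (camera adjusted p = 4.83e-09). Of 10 hypoxia and glycolysis genes 2 rose, VEGFA and BNIP3 at 0.51 (camera adjusted p = 0.00145), and of 6 leukocyte markers 2 rose, LCP1 at 0.61 and CD68 at 0.12 (camera adjusted p = 0.00164). The unfolded protein response, YAP and TAZ targets, apoptosis regulators and p53 targets were lower (camera adjusted p = 6.04e-05, 0.00173, 0.00145 and 0.0154), while a rise of ATF4 and amino acid response genes (camera adjusted p = 0.0279) was lost, at adjusted p = 0.612 with an estimated correlation; the other calls held with it. The remaining 18 lists did not pass, mitosis among them (0 of 17 rose and 0 fell, camera adjusted p = 0.949). In 42.0% to 48.6% of rows the 3 arrays of a group were exactly equal, which sets replicate differences there to 0. A list without a call, mitosis included, is therefore not shown to be unchanged.

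The third pattern is this standing apart of replicate 1. Of the 27 choices of 1 array per group, 1 gave as many genes (804, highest other 7). Replicate 1 was singled out after it stood apart, so this share cannot exclude chance, although the gap to the other choices was wide. The other choices left replicate 1 arrays in the comparison, so their low counts may come partly from a larger error. Noise of separate normalization would not be shared between groups, but the replicate 1 differences correlated across genes at 0.50 or more. A handling or hybridisation batch and a different state of the cells cannot be told apart, since 0 labels name a day or batch; either may be the source.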
